A study of Arabidopsis thaliana with 18 samples.

How the data were processed

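Total RNA from Arabidopsis thaliana was hybridised to 18 Affymetrix AGRONOMICS1 arrays, a whole-genome tiling design for this plant. The arrays fall into 6 groups of 3, made of 2 genotypes at 3 stages. The genotypes are the control line, which the labels call wild type (NIL-DOG1), and the mutant rdo5-1. The stages are siliques at 14 days after pollination, freshly harvested dry seeds, and seeds imbibed for 6 h. The labels describe growth in a chamber with 16 h of light and 8 h of dark, and they call the replicates biological. Group and replicate number of each array were taken from the labels.

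The deposited values are on a log2 scale, 1 per gene and array, and were made with RMA (background correction, quantile normalization and probe summarisation) per the submitters' processing notes. The software version, the probe-set definition and whether the 18 arrays were normalized together are not given in the sources used here. The deposited table holds 30014 genes named by locus code. A TAIR10.1 gene table matched 29464 of these codes and left 550 unmatched. It was used for symbols. Neighbouring genes were taken in order of locus code, and no coordinates are printed because no build is named for the array values. A log2 value of a dim gene contains background, so fold changes of genes near the low end of the scale are compressed.

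Everything else was computed from the deposited values. One linear model with a mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which gave 12 residual degrees of freedom per gene. No gene was filtered out. P-values were adjusted by the Benjamini-Hochberg method over the 30014 genes of a comparison, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes come from this fit unless another setting or a left-out array is named. The comparisons were rdo5-1 against NIL-DOG1 at each stage, dry seeds against siliques and imbibed against dry seeds in each genotype, and the differences of the genotype effect between stages. SE is the standard error of the fitted log2 fold change, and n is 3 arrays per group. The number of arrays limits the precision.

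Gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined; additions are named below or where they appear. The 20 lists were dormancy and seed maturation regulators, Pumilio family, abscisic acid metabolism, abscisic acid signalling, gibberellin metabolism, gibberellin signalling, seed storage proteins and oleosins, late embryogenesis abundant (LEA) proteins, heat shock proteins, cell wall loosening and endosperm weakening, lipid mobilisation and glyoxylate cycle, ribosome biogenesis, photosynthesis, silique valve and secondary wall markers, seed coat flavonoid markers, seed coat mucilage markers, endosperm markers, jasmonate, ethylene, and light and phytochrome. Of 352 members written down, 341 were used, 10 did not match a locus code of the table used here and 1 was dropped because the gene table gives its code another name. ABI5, one of the genes to be named in any case, was not analysed here. The Pumilio list was written knowing that the study had reported on APUM9 and APUM11. A list's members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. List members were also adjusted over the list alone.

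The named genes were RDO5, DOG1, APUM9, APUM11, CYP707A2, NCED6, NCED9, GA3OX1 and ABI3 in each genotype comparison. To these were added the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap (5 each for stages), up to 4 called members per list, the 5 genes of smallest adjusted p in each direction of a stage difference, and called genes near RDO5 and DOG1. Not every gene of that selection is printed. Calls shared between stages were tested with Fisher's exact test per direction. The same test compared the share of called genes among the 200 genes on each side of RDO5 and of DOG1 with the share elsewhere.

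Alternatives were leaving out the 30% of genes with the lowest mean, quantile normalization again, centring each array on its median, eBayes with trend and robust settings, array weights, fitting the arrays compared alone, the replicate number as a block, an absolute log2 fold change of at least 1, windows of 50 and 500 genes, an estimated correlation for the lists, and leaving out each array in turn. The mean of the genotype effect over the 3 stages was a comparison added after seeing the data, and so were list tests under the scalings and without single arrays, with the preset or an estimated correlation, and the position test of genes called at 2 or more stages. The procedure was tested on simulated data built from the stage means and the residual spread of each of the 30014 genes. That spread was 1 value per gene for all stages, so differences in recovery between stages come from the genes and noise drawn. In each comparison 66 or 67 genes were changed by each amount. In the dry seed comparison the procedure recovered 56.7% of genes changed by 0.5 log2 units, 94.0% of those changed by 1 and 98.5% of those changed by 2, with 5.68% false calls. For siliques these shares were 49.3%, 88.1% and 97.0% with 4.29% false calls, and for imbibed seeds 41.8%, 86.6% and 98.5% with 3.21%. In the dry seed simulation all 5 lists shifted by 0.5 were called and 0 of the 15 others. The noise was drawn independently for each gene and the lists were random, so false calls of lists with correlated members were not tested.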

Results

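Transcript levels were measured on 18 arrays, 3 for each combination of genotype and stage. The genotypes were NIL-DOG1, a line named for the dormancy gene DOG1, and rdo5-1, a mutant of RDO5 (REDUCED DORMANCY 5), which encodes a protein of the type 2C phosphatase family. Deposited log2 values ran from 1.89 to 14.67, and array medians from 4.03 to 4.35. Replicate arrays of a group correlated at 0.990 to 0.995 across genes. The first principal component held 84.6% of the variance and the next ones 7.18% and 0.847%.

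RDO5 itself was lower in rdo5-1 at every stage, and DOG1 was called at none. In siliques the RDO5 value was 5.53 ± 0.41 in rdo5-1 and 6.53 ± 0.06 in NIL-DOG1 (SD, n = 3 each), a log2 fold change of -1.001 ± 0.136 (SE; adjusted p = 0.0033). In dry seeds the values were 9.51 ± 0.11 and 10.44 ± 0.03, a change of -0.93 (adjusted p = 0.0085), and in imbibed seeds 8.46 ± 0.03 and 9.80 ± 0.01, a change of -1.34 (adjusted p = 1.6e-04). DOG1, the central seed dormancy gene, differed by 0.02 in siliques (-0.04 after quantile normalization), 0.29 in dry seeds (adjusted p = 0.278) and 0.10 in imbibed seeds (adjusted p = 0.867). In dry seeds the DOG1 values of the genotypes did not overlap, with rdo5-1 higher, and chance gives groups apart in either direction for 10% of genes. The dry seed call of RDO5 was lost without rdo5-1 dry seed array 1 (log2 fold change -0.89, adjusted p = 0.0648) and without array 2 of that group (log2 fold change -0.90, adjusted p = 0.057). With the 6 silique arrays fitted alone, the RDO5 change of -1.001 had an adjusted p of 0.387 (0.00164 to 0.00526 under the scalings, array weights and trend settings).

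APUM9 and APUM11, which encode Pumilio RNA-binding proteins, were the clearest rises among the genes named in every genotype comparison. That the study had reported on both was known beforehand, so their rises are not independent evidence. APUM9 rose by 5.42 ± 0.14 log2 units in imbibed seeds (SE; adjusted p = 1.9e-12), from 3.19 ± 0.11 to 8.62 ± 0.33 (SD, n = 3). In NIL-DOG1 its values lay at the low end of the scale, at percentiles 13.9, 22.4 and 24.1 of all genes in siliques, dry and imbibed seeds, where they contain background, so the size of its rises is uncertain. It rose by 1.31 in siliques (adjusted p = 2.3e-04), and its difference of 0.72 in dry seeds missed the threshold (adjusted p = 0.0584). That difference was called after quantile normalization (0.79; adjusted p = 0.0361), without the dimmest genes (adjusted p = 0.0376), with trend and robust settings (adjusted p = 0.0483) and without rdo5-1 imbibed array 1 or 2 (adjusted p = 0.0184 and 0.0147), and its adjusted p was 0.272 with the 6 arrays fitted alone. APUM11 rose at all 3 stages, by 1.94 ± 0.20 in siliques, 1.76 ± 0.20 in dry seeds and 2.005 ± 0.199 in imbibed seeds (SE; highest adjusted p = 6.0e-04). The abscisic acid 8'-hydroxylase gene CYP707A2, the abscisic acid synthesis genes NCED6 and NCED9, the gibberellin 3-oxidase gene GA3OX1 and the seed regulator ABI3 were called at no stage. Of these, NCED6 in dry seeds had the largest difference, 0.40 ± 0.20 (SE; adjusted p = 0.614), and CYP707A2 in imbibed seeds differed by 0.28 ± 0.09 (adjusted p = 0.302). In both cases the arrays of the genotypes did not overlap, nor did those of GA3OX1 (rdo5-1 higher) and NCED6 (rdo5-1 lower) in imbibed seeds. As for DOG1, chance alone can give such separation. The SE rests on the spread in all groups, and the NCED6 SD was 0.63 in NIL-DOG1 siliques against 0.10 and 0.07 in dry NIL-DOG1 and rdo5-1 seeds.

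**Figure D1:**
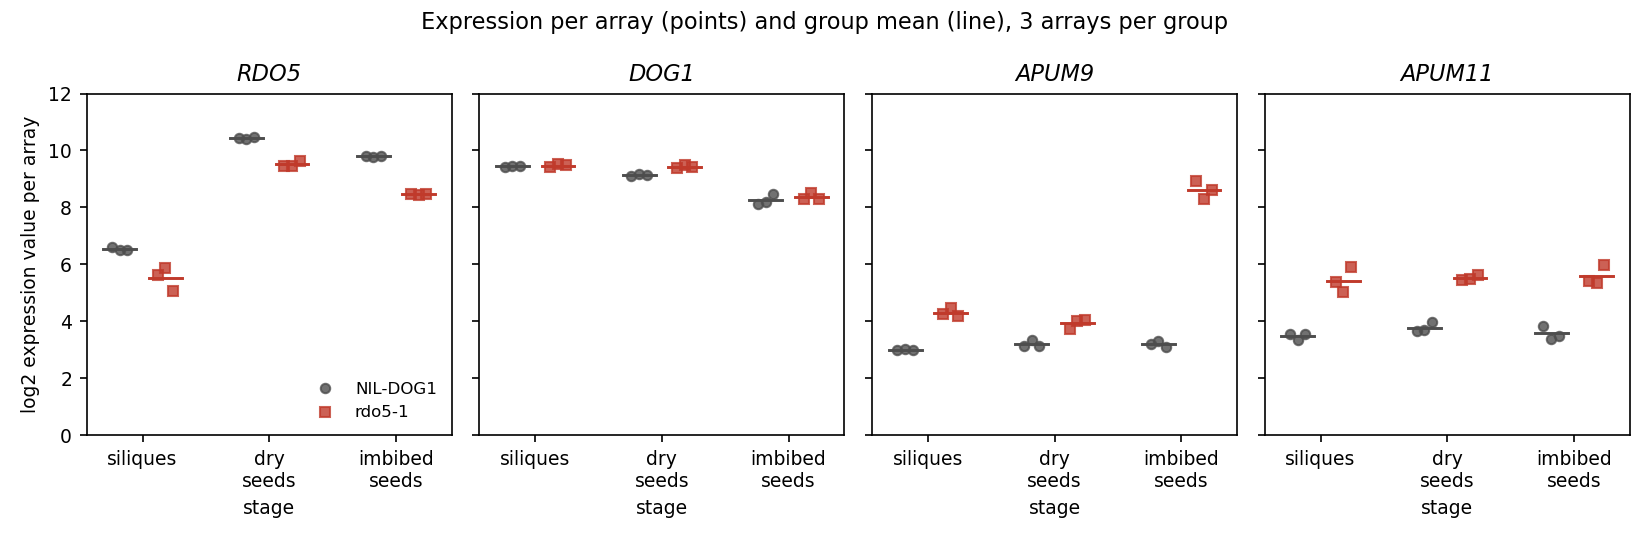
Log2 expression value of RDO5, DOG1, APUM9 and APUM11 on each of the 18 arrays (points) with the mean of each group of 3 (line), by stage and genotype. APUM9 averaged 8.62 in imbibed rdo5-1 seeds against 3.19 in NIL-DOG1, and DOG1 averaged 9.43 and 9.13 in dry seeds.

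In rdo5-1 siliques QQS, an orphan gene involved in carbon and nitrogen allocation, rose by 2.56 ± 0.20, and the F-box gene SDC, which DNA methylation keeps silent in most tissues, rose by 1.64 ± 0.14. Larger rises were found for the uncharacterised AT3G29639 (5.14 ± 0.46), AT2G04460 (4.69 ± 0.25), AT5G35480 (3.78 ± 0.26) and AT4G03930 (2.82 ± 0.19), and DYL1, a gene of the dormancy-associated protein family, rose by 1.95 ± 0.21 (SE, n = 3). The largest falls were AT4G17718 (-1.98 ± 0.29), AT5G19172 (-1.91 ± 0.33) and LCR62 (-1.63 ± 0.22), a small cysteine-rich protein gene. TPX2, here a thioredoxin-dependent peroxidase gene, fell by 0.99, and IAA15, an auxin response repressor, fell by 0.98. AT2G10980 and AT3G43863 rose by 1.91 and 1.33, and AT5G14995 fell by 1.55. The NIL-DOG1 values of AT2G10980 and AT4G03930 lay at percentiles 2.27 and 24.0 of all genes, where the size of a rise is uncertain.

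In all, 60 of the 30014 genes were called in siliques, 32 higher and 28 lower, and 23 of them changed at least 2-fold. An unadjusted p under 0.05 was found for 2667 genes. None of the 20 lists passed in siliques (lowest adjusted p = 0.156; 3 lists had an unadjusted p under 0.05, and 1 with an estimated correlation). Of 18 jasmonate genes, 2 fell, also when adjusted over the list alone: the transcription factor MYC2 (-0.54) and the vegetative storage protein VSP1 (-0.83). Of 9 ribosome biogenesis genes, EIF6A alone was called, 0.33 higher, also over the list alone. The 20 photosynthesis genes had a median difference of 0.11 and the 18 heat shock genes of -0.07, with none called in either. Adjusted over the list alone, 2 photosynthesis genes were higher, and 1 heat shock gene was higher and 4 were lower. The median of the LEA list was -0.12 (28 genes, none called, 1 lower over the list alone), while on NIL-DOG1 silique array 2 that list lay 0.33 above the mean of its partner arrays.

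The count was 38 without NIL-DOG1 silique array 2 and 39 without rdo5-1 silique array 2. Fitted alone, the 6 arrays gave 10, while another split of them in the fit to all 18 arrays gave 66. Of the 25 called genes of the selection, 18 kept their call without each array in turn. AT5G19172 lost it without rdo5-1 silique array 1 (adjusted p = 0.112), and IAA15 (0.0950), EIF6A (0.195), MYC2 (0.0725) and VSP1 (0.173) without rdo5-1 silique array 2.

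Dry rdo5-1 seeds had higher levels of several uncharacterised genes and lower levels of small heat shock protein genes. AT4G04077 rose by 2.81 ± 0.14, AT2G13547 by 2.31 ± 0.22, AT2G11522 by 2.08 ± 0.24 and AT1G67105 by 1.59 ± 0.15 (SE, n = 3). SDC rose by 1.57 ± 0.14 and QQS by 1.31 ± 0.20, and the ethylene response factor gene RAP2.6 rose by 1.18 ± 0.19. AT1G30190 changed by -1.13 ± 0.12, and the small heat shock protein genes HSP17.6B and HSP17.6C changed by -0.65 ± 0.09 and -0.51 ± 0.08. ATMG00570 and ATMG00490 of the mitochondrial genome changed by -0.82 ± 0.12 and -0.74 ± 0.14, and AT2G07716, in a part of chromosome 2 that carries a copy of mitochondrial sequence, fell by 0.94 ± 0.13.

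The heat shock list moved as a group in dry seeds. Of its 18 members 17 were lower, with a median of -0.24 (adjusted p = 1.3e-09; adjusted p = 0.0044 with an estimated correlation); 2 fell by the test over all genes and 7 when adjusted over the list alone. The 19 genes of lipid mobilisation and the glyoxylate cycle had a median of 0.09 with none called, 0 also over the list alone (adjusted p = 0.0061, and adjusted p = 0.631 with an estimated correlation); the first of these was 0.257 without NIL-DOG1 dry seed array 3 and 0.0567 without rdo5-1 dry seed array 2. The other 18 lists did not pass. Members of the lists accounted for 4 of the calls: RDO5, APUM11 and the pair of heat shock genes.

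A total of 41 genes were called in dry seeds, 27 higher and 14 lower, 12 of them by at least 2-fold. In this comparison 2504 genes had an unadjusted p under 0.05. The count was 25 without NIL-DOG1 dry seed array 1, 25 without array 2 and 27 without array 3, 19 without rdo5-1 dry seed array 1, 21 without its array 2 and 26 without rdo5-1 imbibed seed array 1. It was 6 with the 6 arrays alone and 64 without the dimmest genes. Of the 23 called genes of the selection 11 kept their call without each array in turn, among them AT4G04077, SDC, APUM11 and HSP17.6B. QQS (adjusted p = 0.0655), RAP2.6 (0.107) and HSP17.6C (0.101) lost it without rdo5-1 dry seed array 2, and ATMG00570 (0.0691) and ATMG00490 (0.190) without array 1.

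In imbibed rdo5-1 seeds most of the called genes were higher. Beside APUM9, AT4G04077 rose by 3.22 ± 0.14, AT2G13547 by 2.44 ± 0.22, AT1G21520 by 2.07 ± 0.27 and AT1G67105 by 1.77 ± 0.15 (SE, n = 3). The glutathione transferase gene GSTU22 rose by 1.88 ± 0.21 and QQS by 1.66 ± 0.20. Among hormone genes, the gibberellin 20-oxidase gene GA20OX3 rose by 1.196 ± 0.13, and the abscisic acid receptor genes PYR1 and PYL4 by 0.87 ± 0.09 and 0.88 ± 0.13. The transcription factor gene ABI4 rose by 0.59 ± 0.11, while HAI1, a type 2C phosphatase gene of abscisic acid signalling, fell by 0.70 ± 0.12. AT1G30190 changed by -1.09 ± 0.12, AT5G65533 by -0.96 ± 0.12 and AT4G37180 by -0.86 ± 0.11.

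The heat shock list was again lower in imbibed rdo5-1 seeds: 16 of 18 members were below NIL-DOG1, with a median of -0.31 (adjusted p = 1.5e-10; adjusted p = 0.0029 with an estimated correlation). HSP21 changed by -0.84, HSP17.6B by -0.60 and HSP101, a disaggregase gene, by -0.43; adjusted over the list alone 9 fell. The test of the difference gave adjusted p = 2.2e-04 for the list in dry seeds against siliques (adjusted p = 0.0866 with an estimated correlation), 2.7e-04 for imbibed seeds against siliques (adjusted p = 0.0464 with an estimated correlation) and 0.937 for imbibed against dry seeds. With an estimated correlation the imbibed seed and silique difference lost its call without any of 13 arrays (highest adjusted p = 0.123, without rdo5-1 silique array 2) and after centring (adjusted p = 0.0845). In NIL-DOG1 siliques HSFA9, HSP22 and HSP17.6B lay at percentiles 28.1, 39.2 and 42.4 of all genes, against 98.4, 85.9 and 96.5 in dry seeds. Others, such as HSP17.4 and HSP70 (87.0 and 91.3), were bright in siliques. For the dim members a smaller silique effect cannot be told apart from compressed fold changes.

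**Figure D2:**
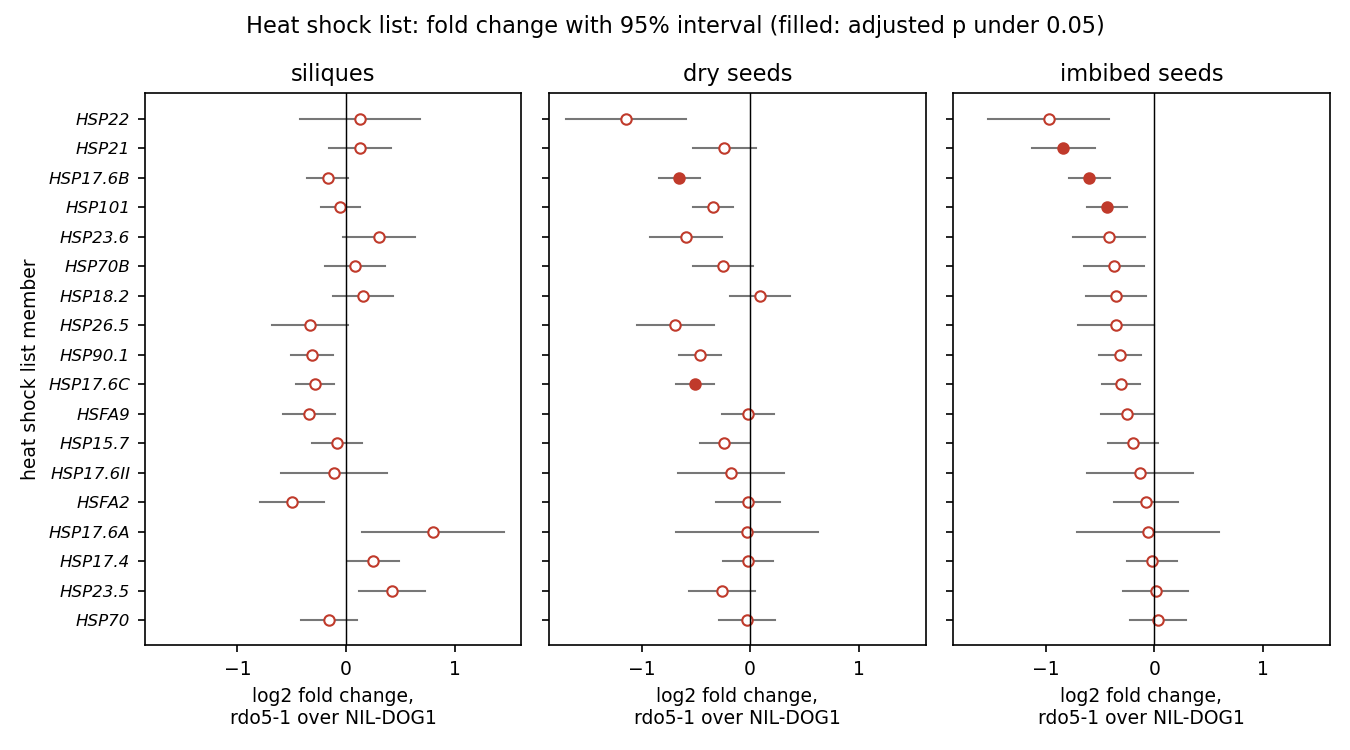
Log2 fold change of rdo5-1 over NIL-DOG1 (horizontal axis) for the 18 heat shock list members at the 3 stages, with 95% intervals and filled points where the adjusted p over all genes was under 0.05. Members were lower for 10 of 18 in siliques, 17 in dry seeds and 16 in imbibed seeds.

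The cell wall, jasmonate, gibberellin signalling and Pumilio lists had positive medians in imbibed seeds, also under both scalings, and each lost its call with an estimated correlation; gibberellin signalling also lost it after quantile normalization (adjusted p = 0.0777). Of 15 genes of cell wall loosening and endosperm weakening, the expansin gene EXPA8 rose by 0.80 (3 rose over the list alone), with a list median of 0.10 (adjusted p = 0.0025, and adjusted p = 0.0799 with an estimated correlation). Of 18 jasmonate genes, the repressor gene JAZ1 rose by 0.43 (2 over the list alone), with a median of 0.11 (adjusted p = 0.0242, and adjusted p = 0.0799 with an estimated correlation). The jasmonate effect differed from that in siliques (adjusted p = 6.1e-04; adjusted p = 0.0410 with an estimated correlation, a call that ended without any of 11 arrays, at most 0.123 without rdo5-1 silique array 2, and after centring, 0.0673). The 12 gibberellin signalling genes had a median of 0.13 with none called, over the list alone either (adjusted p = 0.0253, and adjusted p = 0.0799 with an estimated correlation). The Pumilio list, not independent evidence because it was written knowing the study's report, held 2 rises, APUM9 and APUM11, and 3 over the list alone (adjusted p = 0.0201, and adjusted p = 0.0799 with an estimated correlation); its median was 0.02. Without NIL-DOG1 imbibed array 3 the Pumilio, jasmonate and gibberellin signalling p-values were 0.172, 0.0842 and 0.0663, and without rdo5-1 imbibed array 3 they were 0.0542, 0.0566 and 0.0821. Without rdo5-1 imbibed array 2 the jasmonate p was 0.0550.

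Of 32 abscisic acid signalling genes, 3 rose and 1 fell (6 and 5 over the list alone), and of 21 gibberellin metabolism genes 1 rose (2 over the list alone); neither list passed (adjusted p = 0.476 and 0.0547). One of 28 LEA genes, SAG21, rose by 1.17, and of 28 dormancy regulators ABI4 rose and RDO5 fell (4 and 3 over the list alone). None was called among the 14 abscisic acid metabolism, 15 seed storage, 19 lipid mobilisation, 9 ribosome biogenesis, 20 photosynthesis, 13 silique valve, 18 seed coat flavonoid, 11 seed coat mucilage, 8 endosperm, 10 ethylene and 8 light genes; over the list alone 2 storage genes and 1 photosynthesis gene were lower.

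Imbibed seeds gave 190 called genes, 152 higher (80.0%) and 38 lower, 34 of them by at least 2-fold, and 2495 with an unadjusted p under 0.05. Leaving out 1 array gave 82 and 92 (rdo5-1 imbibed arrays 1 and 3) and 94, 122 and 105 (NIL-DOG1 imbibed arrays 1, 2 and 3), the 6 arrays alone gave 48, and array weights gave 413. Of the 32 called genes of the selection, 21 kept their call without each array in turn. SAG21 (adjusted p = 0.109), HAI1 (0.0715), HSP21 (0.0537) and JAZ1 (0.187) lost it without rdo5-1 imbibed array 1, ABI4 (0.0964) without array 3 and HSP101 (0.145) without NIL-DOG1 imbibed array 1.

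Some genes differed at more than 1 stage. SDC, QQS, AT3G29639, AT4G04077 and APUM11 were higher at all 3 stages, and RDO5, AT2G07716 and ATMG00570 were lower at all 3. AT3G29639 rose by 5.14 in siliques, 2.497 in dry seeds and 2.196 in imbibed seeds; its dry seed call was lost without NIL-DOG1 dry seed array 2 (adjusted p = 0.163) and its imbibed seed call without rdo5-1 imbibed array 1 (adjusted p = 0.179). Of the 257 genes called at any stage, 26 were called at 2 or more, and 0 went in opposite directions. Dry and imbibed seeds shared 19 of their higher and 6 of their lower calls, where 0.14 and 0.018 would be shared by independent lists (Fisher's exact test, p = 1.6e-38 and 8.1e-15). Siliques shared 5 higher and 3 lower calls with dry seeds (expected 0.029 and 0.013; Fisher's exact test, p = 7.9e-11 and 2.6e-07) and 6 and 3 with imbibed seeds (expected 0.16 and 0.035; p = 1.2e-08 and 6.0e-06). All stages share 1 estimate of the spread per gene, so a gene of small spread is more easily called at every stage. These Fisher p-values take no account of that, and fewer calls were shared with the arrays compared fitted alone. The 3 lower calls that siliques shared with either seed stage were RDO5 (the mutated gene), AT2G07716 and ATMG00570. AT2G07716 and ATMG00570 averaged 7.53 and 7.50 in dry NIL-DOG1 seeds, and 6.59 and 6.68 in dry rdo5-1 seeds. These 2 may therefore not count as independent genes. Over all genes, which are not independent replicates, the fold changes correlated weakly, at 0.09 for siliques and dry seeds, 0.06 for siliques and imbibed seeds and 0.15 for dry and imbibed seeds.

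At no single stage did a test of position pass around RDO5 or DOG1, while genes called at 2 or more stages were more frequent within 500 genes of RDO5 (3 of 25; odds ratio 3.97; Fisher's exact p = 0.0492), a test chosen after the values were seen. Among the 200 genes on each side of RDO5, taken in order of locus code, 1 was called in siliques (AT4G11911, 0.68 higher), and AT4G09580 and KELP were called in dry seeds (0.92 and 0.47 higher) and in imbibed seeds (0.49 and 0.44 higher). The odds ratios against the rest of the genes were 1.28, 3.91 and 0.79 (two-sided Fisher's exact test, p = 0.547, 0.0993 and 1). With 50 genes on each side the dry seed ratio was 7.74 (Fisher's exact p = 0.125). KELP lost its dry seed call without NIL-DOG1 dry seed array 1 (adjusted p = 0.143) and its imbibed seed call without NIL-DOG1 imbibed array 3 (adjusted p = 0.123). Beside DOG1, 0 of 400 genes were called at any stage by limma (lowest Fisher's exact p = 0.189).

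From siliques to dry seeds of NIL-DOG1, desiccation and heat shock genes rose and photosynthesis genes fell. The first samples were siliques and the later ones seeds, so tissue and stage cannot be told apart in these changes, in either genotype. The LEA genes M17, ECP31 and EM6 rose by 9.498 ± 0.302, 9.38 ± 0.25 and 8.90 ± 0.40, and 25 of 28 LEA genes rose while 1 fell (median 3.57; adjusted p = 4.9e-13, and adjusted p = 0.0324 with an estimated correlation). All 18 heat shock genes rose (median 4.43; adjusted p = 6.6e-04 with an estimated correlation), with HSP17.6A by 8.86 ± 0.31 and the seed heat shock factor HSFA9 by 7.33 ± 0.11. All 20 photosynthesis genes fell (median -5.54; adjusted p = 1.7e-04 with an estimated correlation), among them the antenna protein genes LHCA2 (-7.57 ± 0.16) and LHCB3 (-7.13 ± 0.15; SE, n = 3). AT1G62060 had the largest fall, -9.94 ± 0.32. On their lower side HSFA9 (siliques) and AT1G62060 (dry seeds) lay at percentiles 28.1 and 28.2 of all genes, near the low end of the scale, so the size of these changes is uncertain. Of 19 lipid mobilisation genes 16 rose and 2 fell (median 1.27; adjusted p = 0.0434 with an estimated correlation), with the glyoxylate cycle genes MLS and ICL up by 5.80 and 3.16. The LEA call with an estimated correlation ended without rdo5-1 silique array 3 (adjusted p = 0.0542), after quantile normalization (adjusted p = 0.0508) and after centring (adjusted p = 0.0772). The lipid mobilisation call, at adjusted p = 2.3e-06 with the preset correlation, ended with an estimated one without any of 7 arrays (highest adjusted p = 0.0620, without NIL-DOG1 silique array 2), after quantile normalization (adjusted p = 0.0912) and after centring (adjusted p = 0.171).

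The silique valve, mucilage and jasmonate lists fell over the same interval. Of 13 silique valve genes 11 fell (median -0.77; adjusted p = 0.0168 with an estimated correlation), with the polygalacturonase gene ADPG1 at -6.40, and of 11 mucilage genes 8 fell and 1 rose (median -1.41; adjusted p = 0.0355 with an estimated correlation). Of 18 jasmonate genes 12 fell and 4 rose (median -1.23; adjusted p = 0.0355 with an estimated correlation), and VSP1 fell by 7.96. In dry seeds ADPG1 and VSP1 lay at percentiles 25.4 and 28.1 of all genes, so the size of these falls is uncertain too. The mucilage and jasmonate calls with an estimated correlation ended without rdo5-1 silique array 2 (adjusted p = 0.0566 for both), and the mucilage call also without array 3 of that group (adjusted p = 0.0531) and after quantile normalization (adjusted p = 0.0626). Of 18 flavonoid genes 12 fell (median -0.91; adjusted p = 5.6e-05, and adjusted p = 0.0697 with an estimated correlation), and the laccase gene TT10 fell by 6.13. All 9 ribosome biogenesis genes rose (median 1.61; adjusted p = 9.1e-06, and adjusted p = 0.0710 with an estimated correlation), and 7 of 8 light genes rose and 1 fell (median 0.77; adjusted p = 0.0077, and adjusted p = 0.0697 with an estimated correlation). The 15 storage protein genes had a median of -0.24, with 8 falls and 2 rises (adjusted p = 0.0243, and adjusted p = 0.383 with an estimated correlation); after centring the median was 0.01, with 5 falls and 7 rises, and the adjusted p 0.287. Over each of these lists alone the counts on the deposited values were the same, except that 1 flavonoid gene also rose.

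Dormancy, abscisic acid and gibberellin genes moved in both directions, and their lists did not pass. RDO5 rose by 3.91 ± 0.14 from siliques to dry seeds of NIL-DOG1, the phosphatase gene AHG1 by 4.91, the germination repressor gene SOM by 4.63 and the abscisic acid receptor gene PYL11 by 6.15; 14 dormancy genes rose and 10 fell (14 and 11 over the list alone; adjusted p = 0.246). CYP707A2 rose by 1.57 and NCED6 fell by 2.29, with 7 rises and 5 falls among 14 abscisic acid metabolism genes (adjusted p = 0.712), and 17 abscisic acid signalling genes rose and 12 fell (adjusted p = 0.271). GA20OX3 changed by -5.45 and the gibberellin-regulated GASA6 by -6.05; gibberellin metabolism genes rose in 4 and fell in 8 cases, signalling genes in 4 and 6 (adjusted p = 0.141 and 0.928). After centring both medians, -0.13 and -0.20, turned positive, with 7 rises and 6 falls for metabolism and 5 and 4 for signalling, whose median was also positive after quantile normalization (0.06; 5 and 5). Of the Pumilio genes 7 rose and 3 fell (16 and 1 after centring, 9 and 2 after quantile normalization; adjusted p = 0.131). Of cell wall loosening genes 3 rose and 7 fell (adjusted p = 0.0571; the median of -0.10 turned positive under both scalings), of ethylene genes 4 and 3 (adjusted p = 0.781) and of endosperm genes 2 and 1 (7 and 0 after centring, 2 and 0 after quantile normalization; adjusted p = 0.781).

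Altogether 16209 genes differed between dry seeds and siliques of NIL-DOG1, 8231 higher (50.8%) and 7978 lower; 6656 changed at least 2-fold. The array medians of dry seeds stood at -0.25 relative to siliques in NIL-DOG1 and -0.23 in rdo5-1. The median change over all genes was 0.05 in NIL-DOG1 and 0.06 in rdo5-1, so the typical gene did not fall. Centring the arrays on their medians removed the difference in array medians and so raised the change of every gene by its size. It gave 21806 calls in NIL-DOG1, 72.4% of them higher. Quantile normalization gave 57.1% higher, so the split into higher and lower depends on the scaling.

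In rdo5-1 the same interval gave 15879 called genes, 8159 higher (51.4%; 71.3% of 21276 after centring) and 7720 lower. RDO5 rose by 3.98 ± 0.14, M17 by 8.98 ± 0.30 and HSFA9 by 7.65 ± 0.11, and LHCA2 fell by 7.38 ± 0.16 (SE, n = 3); HSFA9 started from percentile 14.0 of all genes in siliques. The LEA list rose (25 of 28, 1 lower; median 3.73; adjusted p = 0.0259 with an estimated correlation), as did heat shock (17 of 18; median 4.14; adjusted p = 9.3e-04 with an estimated correlation), while 19 of 20 photosynthesis genes fell (median -5.69; adjusted p = 1.6e-04 with an estimated correlation). Lipid mobilisation genes rose in 16 cases and fell in 2 (median 1.28; adjusted p = 0.0411 with an estimated correlation), 9 of 13 silique valve genes fell (median -0.81; adjusted p = 0.0259 with an estimated correlation), 8 of 11 mucilage genes fell and 1 rose (median -1.55; adjusted p = 0.0411 with an estimated correlation), and 12 of 18 jasmonate genes fell and 5 rose (median -1.30; adjusted p = 0.0411 with an estimated correlation). With an estimated correlation the lipid mobilisation, mucilage and jasmonate calls ended without any of 7, 4 and 7 arrays (highest adjusted p = 0.0567, 0.0567 and 0.0620, each without rdo5-1 silique array 2). After quantile normalization lipid mobilisation had 0.0785 and mucilage 0.0610, and after centring lipid mobilisation had 0.153 and LEA 0.0580. The 2 genotypes shared 6968 higher and 7104 lower calls, and their fold changes correlated at 0.98 across genes.

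Over 6 h of imbibition of NIL-DOG1 seeds CHS, the gene of chalcone synthase, rose by 5.24 ± 0.15, FLS1 by 4.96 ± 0.14 and TT7 by 4.24 ± 0.13, while the kinase gene MAPKKK19 changed by -4.29 ± 0.13 and RAP2.6 by -4.04 ± 0.19 (SE, n = 3). Of 18 flavonoid genes 6 rose and none fell, also over the list alone; the mean was 1.14 but the median -0.003 (0.04 after quantile normalization and 0.02 after centring; adjusted p = 0.0017, and adjusted p = 0.260 with an estimated correlation). Of 9 ribosome biogenesis genes 8 rose, also over the list alone, with the fibrillarin gene FIB2 by 2.75 (median 0.95; adjusted p = 2.8e-08, and adjusted p = 0.0518 with an estimated correlation). Of 18 heat shock genes 9 rose and 1 fell, also over the list alone (median 0.42; adjusted p = 2.4e-05, and adjusted p = 0.0272 with an estimated correlation), and of 18 jasmonate genes 8 fell and 1 rose, 10 and 1 over the list alone (median -0.27; adjusted p = 1.5e-04, and adjusted p = 0.0272 with an estimated correlation), with JAZ10 at -2.601. The heat shock call with an estimated correlation ended without rdo5-1 silique array 1 (adjusted p = 0.0552) or 2 (adjusted p = 0.0510) and after centring (adjusted p = 0.0523), and the jasmonate call without rdo5-1 silique array 2 (adjusted p = 0.0510). Of 10 ethylene genes 4 fell (median -0.21; adjusted p = 0.0109, and adjusted p = 0.0518 with an estimated correlation) and of 28 LEA genes 5 (median -0.09; adjusted p = 0.0377, and adjusted p = 0.580 with an estimated correlation), with the same counts over each list alone; the LEA p was 0.0760 and 0.0801 without NIL-DOG1 imbibed arrays 1 and 2, and 0.0597 and 0.0509 without NIL-DOG1 dry seed arrays 2 and 3.

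Dormancy, abscisic acid and gibberellin genes again moved both ways during imbibition of NIL-DOG1 seeds. DOG1 changed by -0.86 ± 0.09, SOM by -0.96 ± 0.16 and the phosphatase gene ABI1 by -1.99 ± 0.10, while the phytochrome-interacting factor gene PIF1 rose by 1.73 ± 0.09, PYL4 by 2.09 ± 0.13 and the DELLA gene RGL2 by 1.56 ± 0.10 (SE, n = 3). Of 28 dormancy genes 2 rose and 9 fell (3 and 10 over the list alone; adjusted p = 0.171). The comparison gave 7460 called genes, 4265 higher and 3195 lower, 957 of them by at least 2-fold.

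In rdo5-1 imbibition changed 8496 genes, 4932 higher and 3564 lower, 1145 of them by at least 2-fold. CHS rose by 5.62 ± 0.15, APUM9 by 4.69 ± 0.14, GA20OX3 by 1.87 ± 0.13 and ABI4 by 1.23 ± 0.11, and DOG1 fell by 1.05 ± 0.09 (SE, n = 3). Ribosome biogenesis genes rose in 8 of 9 cases, also over the list alone (median 0.95; adjusted p = 8.9e-08, and adjusted p = 0.0825 with an estimated correlation). Heat shock genes rose in 8 and fell in 2 cases, 9 and 2 over the list alone (adjusted p = 4.1e-04, and adjusted p = 0.0669 with an estimated correlation). Jasmonate genes fell in 9 cases and rose in 1 (median -0.25; adjusted p = 0.0032, and adjusted p = 0.0669 with an estimated correlation), 6 of 28 LEA genes fell (adjusted p = 0.0218, and adjusted p = 0.450 with an estimated correlation), and 6 of 18 flavonoid genes rose while 1 fell (adjusted p = 0.0086, and adjusted p = 0.361 with an estimated correlation). The LEA p was 0.0891 without rdo5-1 imbibed array 2 and 0.0582 after quantile normalization. The genotypes shared 3746 higher and 2393 lower calls, with a correlation of 0.85 across genes.

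**Figure D3:**
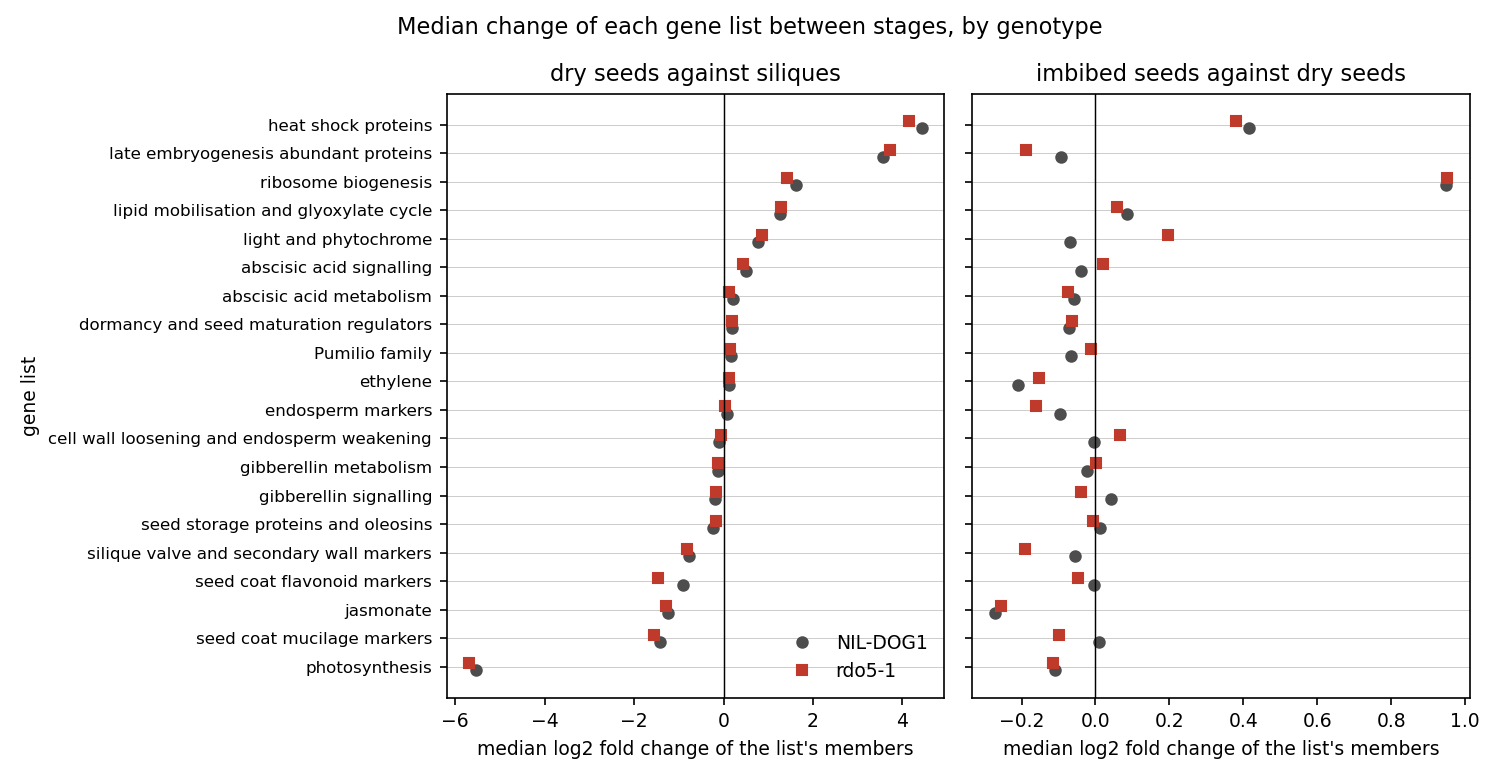
Median log2 fold change of each of the 20 gene lists (vertical axis) from siliques to dry seeds and from dry to imbibed seeds, in NIL-DOG1 and rdo5-1. The LEA median was 3.57 in NIL-DOG1 and 3.73 in rdo5-1 from siliques to dry seeds, the photosynthesis median -5.54 and -5.69; over that interval the negative medians of the gibberellin, storage and cell wall lists turned positive after centring.

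The rdo5-1 effect itself differed between stages for few genes. The APUM9 effect was larger in imbibed than in dry seeds by 4.70 ± 0.19 (SE; adjusted p = 3.1e-09) and larger than in siliques by 4.11 ± 0.19 (adjusted p = 2.3e-08). The effects on AT2G04460, AT4G03930 and AT5G35480 were lower in dry seeds than in siliques, by -4.19, -2.85 and -3.24. The test of the difference called 15 genes for dry seeds against siliques (8 higher, 7 lower), 31 for imbibed seeds against siliques (19 higher, 12 lower) and 6 for imbibed against dry seeds (5 higher, 1 lower). The count of 6 was 1 without NIL-DOG1 dry seed array 1 and 10 without rdo5-1 imbibed array 2, and the count of 31 was 18 without rdo5-1 silique array 1 and 63 without rdo5-1 imbibed array 2.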

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

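The tests used to weigh the 3 patterns below were chosen only after those results were seen, while the tests of the difference between stages and the other splits of the arrays were planned.

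The difference of the rdo5-1 effect between stages drew attention to several genes. Between dry seeds and siliques 15 genes passed that test. The effect was larger in dry seeds for AT4G09580 (by 0.89), AT5G27850 (0.88), AT4G04077 (1.72), AT2G13547 (2.39) and the senescence-associated SEN1 (0.94), and lower for AT2G04460 (-4.19), AT4G03930 (-2.85), AT5G35480 (-3.24), AT2G10980 (-1.82) and AT3G20460 (-1.02). Of 100 splits of the arrays within stages, 1 gave as many genes, the real one, and the highest other gave 10. The splits mix the genotypes at every stage and so stand for no genotype effect at all. They cannot decide whether chance gave this count of differences between stages. The jasmonate and flavonoid lists also passed the difference test here (adjusted p = 0.0200, and adjusted p = 0.107 with an estimated correlation; adjusted p = 0.0262, and adjusted p = 0.686 with an estimated correlation).

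Between imbibed and dry seeds 6 genes passed the test of the difference: APUM9 (4.70), HB33 (0.71), GSTU22 (2.08), AT2G24560 (0.85), PYR1 (0.86) and AT5G65533 (-1.09). Of 100 splits 8 gave as many, with 12 in the highest other, so chance cannot be excluded for this count. APUM9 passed without each array in turn (highest adjusted p = 4.7e-08). Without rdo5-1 imbibed array 3, HB33, AT2G24560, PYR1 and AT5G65533 had an adjusted p of 0.160, and without rdo5-1 dry seed array 1 GSTU22 had 0.133.

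Between imbibed seeds and siliques 31 genes passed, among them APUM9 (4.11), HB33 (1.05), AT4G04077 (2.13), AT5G27850 (0.96), AT2G13547 (2.525), AT2G04460 (-4.78), AT4G03930 (-3.22), AT5G35480 (-4.08), AT2G10980 (-2.06) and AT1G67856 (-0.92). Of 100 splits 2 gave as many genes, the real one included, and the highest other gave 39. Chance is not excluded for this count, since 1 other split exceeded it and the splits mix the genotypes at every stage. The count was 20 without rdo5-1 imbibed array 1, 63 without array 2, 20 without array 3 and 18 without rdo5-1 silique array 1.

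For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. In siliques the real split gave 60 genes and the highest other 66, so 2 of the 10 splits gave as many. In dry seeds the real split gave 41 and the highest other 3, and in imbibed seeds 190 and 1; in each, 1 split, the real one, gave as many. The stage comparisons gave 16209 against 1 and 7460 against 0 in NIL-DOG1, and 15879 against 0 and 8496 against 0 in rdo5-1.

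Besides RDO5, 25 genes were called at 2 or more stages, and a sequence difference between the lines was weighed as a source. Of the 25, 3 (12%) lie within 500 genes of RDO5, against 3.33% of all genes (odds ratio 3.97, Fisher's exact p = 0.0492). Place cannot decide on a variant linked to RDO5 for the whole set, since such a variant could also change genes elsewhere. For those 3, APUM11, AT4G09580 and KELP, linkage may contribute and cannot be told apart from an effect of rdo5-1, because the sources used here do not state whether the lines also differ in sequence there. Strain variants under the probes of these genes cannot be told apart from a change in the transcript, since 0 of the 25 were called higher at one stage and lower at another and both would give that.

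On an axis made from the NIL-DOG1 change between dry and imbibed seeds, rdo5-1 imbibed seeds lay further along, by 0.0453 of the axis, with each of the 3 rdo5-1 arrays above the held-out NIL-DOG1 array in all 3 rounds. The rounds used the same 3 rdo5-1 arrays, and the held-out NIL-DOG1 imbibed array itself scored from 0.782 to 0.827. A wider spread of values on the rdo5-1 imbibed arrays was argued against, since 77.5% of the excess was kept after every array was given the same distribution. The mean excess in dry seeds was -0.0033, so the lines did not already differ by that much before imbibition. That rdo5-1 seeds had progressed further in 6 h may be a biological explanation, held as a hypothesis because it was found and tested on the same arrays.

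NIL-DOG1 silique array 2 lay apart from its partners, and its deviation correlated across genes with the rdo5-1 change from siliques to dry seeds at 0.248. Random noise was argued against, since the rdo5-1 silique arrays reached 0.03, 0.09 and -0.12 with the NIL-DOG1 change. A later harvest could explain it, with the LEA list at 0.33 above its partners, but cannot be told apart from other sources because the photosynthesis list was not below them (0.02). The deviations of this array and of rdo5-1 silique array 2 correlated at 0.169 across genes. Without this NIL-DOG1 array 38 genes were called in siliques in place of 60.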

How the results depend on the processing

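The list tests under the scalings and without single arrays, and all tests of the mean over stages, were chosen only after the data were seen. All other alternatives were planned. The causes of the changes below were not tested, except where fewer genes or arrays make them.

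With the arrays compared fitted alone, and so fewer degrees of freedom, 10 genes were called in siliques, 6 in dry seeds and 48 in imbibed seeds, and 1 for the difference of imbibed against dry seeds. RDO5 in siliques kept its change of -1.0008 but not its call (adjusted p = 0.387). Shared calls fell to 1 for siliques and dry seeds, 4 for siliques and imbibed seeds and 4 for dry and imbibed seeds. Without the dimmest 30% of genes, 64 genes were called in dry seeds and 58 for the difference of imbibed seeds against siliques. That difference gave 52 with trend and robust settings and 64 with array weights, and imbibed seeds gave 413 with array weights, which ran from 0.544 (NIL-DOG1 silique array 2) to 1.67 (rdo5-1 imbibed array 1).

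With a log2 change of at least 1, which can only remove genes, the counts were 23, 12 and 34 for siliques, dry and imbibed seeds, 6656 and 957 for the stages of NIL-DOG1, 6599 and 1145 for those of rdo5-1, 3 and 17 for the differences of imbibed seeds against dry seeds and siliques, and 14 for the mean over stages.

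With the replicate number as a block, 1 gene was called for the difference of imbibed against dry seeds. Taken over all groups, replicate numbers gave little sign of pairing the arrays. Of 45 pairs of arrays with the same number in different groups, 1 had deviations correlated above 0.1 (NIL-DOG1 and rdo5-1 silique arrays 2, at 0.169). The median was -0.002, and the best match had the same number in 22 of 90 checks. Silique arrays 1 and 3 of the genotypes had 0.0018 and 0.0841, and silique pairs of different number ran from -0.151 to 0.0843. Pairing within siliques is therefore not ruled out. With this block 18 results of named genes lost their call and 415 kept side and direction, a gene counting once for each comparison.

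DOG1 in siliques was -0.044 after quantile normalization. Among genes never called, NCED9 in siliques was 4.5e-05 after centring, GA3OX1 0.030 in siliques without single arrays and 0.0046 in dry seeds with array weights, and ABI3 in dry seeds 0.018 (quantile), 3.1e-04 (array weights) and 0.0034 (single arrays left out), and -0.0050 in imbibed seeds without single arrays. Odds ratios changed side for 50 genes around RDO5 in siliques (0) and imbibed seeds (1.60) and for 500 around DOG1 in siliques (1.53).

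With an estimated correlation, adjusted p rose to 0.631 for lipid mobilisation in dry seeds and 0.0799 for the Pumilio, gibberellin signalling, cell wall and jasmonate lists in imbibed seeds. From siliques to dry seeds it was 0.383 (storage), 0.0710 (ribosome biogenesis), 0.0697 (flavonoid) and 0.0697 (light) in NIL-DOG1, and 0.406, 0.0708, 0.0631 and 0.0632 in rdo5-1. For imbibition it was 0.580 (LEA), 0.0518 (ribosome biogenesis), 0.260 (flavonoid) and 0.0518 (ethylene) in NIL-DOG1, and 0.450 (LEA), 0.0669 (heat shock), 0.0825 (ribosome biogenesis), 0.361 (flavonoid) and 0.0669 (jasmonate) in rdo5-1. Quantile normalization gave 0.0777 for gibberellin signalling in imbibed seeds and 0.0582 for LEA in rdo5-1 imbibition, and centring 0.287 and 0.366 for storage from siliques to dry seeds of NIL-DOG1 and rdo5-1. With an estimated correlation and the replicate block, it was 0.0627 and 0.0605 for lipid mobilisation and 0.0542 and 0.0605 for jasmonate from siliques to dry seeds of NIL-DOG1 and rdo5-1, 0.0630 for heat shock in NIL-DOG1 imbibition, and 0.118 and 0.0716 for the heat shock and jasmonate differences of imbibed seeds against siliques. Heat shock in dry and imbibed seeds kept its direction and call under these settings and without each array, with either correlation.

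Leaving out 1 array at a time, counts ran from 38 to 78 in siliques, 19 to 41 in dry seeds, 82 to 195 in imbibed seeds, 15366 to 16241 and 6440 to 7665 for the stages of NIL-DOG1, and 15055 to 15948 and 7211 to 8716 for those of rdo5-1. For the differences they ran from 12 to 21 (dry seeds against siliques), 1 to 10 (imbibed against dry seeds) and 18 to 63 (imbibed seeds against siliques). The mean over stages ran from 166 to 291. The RDO5 change ran from -1.18 to -0.78 in siliques, -0.99 to -0.89 in dry seeds and -1.35 to -1.33 in imbibed seeds. List p-values ran from 0.0033 to 0.257 (lipid mobilisation, dry seeds), 0.0033 to 0.172 (Pumilio, imbibed), 0.0079 to 0.0821 (gibberellin signalling, imbibed), 0.0183 to 0.0842 (jasmonate, imbibed), 0.0173 to 0.0801 (LEA, NIL-DOG1 imbibition), 0.0311 to 0.0668 (storage, rdo5-1 dry seeds against siliques) and 0.0111 to 0.0891 (LEA, rdo5-1 imbibition).

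Of the results of named genes, a gene counting once for each comparison, 47 lost their call without some array, 61 with the arrays compared fitted alone, 11 after quantile normalization, 7 after centring and 3 with array weights, and 1 gained it under each of quantile normalization, trend and robust settings, and leaving out the dimmest genes. With 3 arrays per group the simulation recovered 49.3%, 56.7% and 41.8% of changes of 0.5 in siliques, dry and imbibed seeds. Each gene had the same spread at all stages, so these shares do not rank the stages by sensitivity. It did not separate genes by their signal over background.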

Other observations

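Every gene set, test and comparison in this part was chosen only after the values were seen.

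Some genes outside the lists were picked from those called in imbibed rdo5-1 seeds, and no test of a group was made on them. The glutathione transferase gene GSTU24 rose by 1.59 ± 0.22, the glycosyltransferase gene UGT73B4 by 1.46 ± 0.24, the alternative oxidase gene AOX1A by 1.11 ± 0.20, WRKY33 by 0.96 ± 0.16 and WRKY25 by 0.76 ± 0.14 (SE, n = 3; highest adjusted p = 0.0171).

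The 23 genes of the 20S proteasome were all higher in imbibed rdo5-1 seeds, with a median of 0.25 and 4 called: PAA2 (0.51), PBB2 (0.42), PAD1 (0.39) and PBC1 (0.33). The list gave p = 2.8e-04 by camera with an estimated correlation, and p = 0.0021 for 15 members after the 8 called here or in the mean over stages had been left out. In siliques and dry seeds 21 and 19 of them were higher, with none called by limma, and the camera test with an estimated correlation missed the threshold (0.0896 and 0.0589).

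Averaged over the 3 stages, the rdo5-1 effect was called for 285 genes, 183 higher (64.2%; 52.4% after quantile normalization) and 102 lower, of which 136 were called at no single stage. The highest count among the other splits was 8, and 1 of 100 splits, the real one, gave as many genes. Chance is not excluded by this, since the comparison was chosen after the values were seen and the splits mix the genotypes at every stage. The count was 186 and 182 without NIL-DOG1 imbibed arrays 1 and 2, 168 and 187 without rdo5-1 dry seed arrays 1 and 2, and 168 and 166 without rdo5-1 imbibed arrays 1 and 3. Among the 285 were SDC (1.35) and QQS (1.84), and 3 higher and 3 lower genes of the 32 in the abscisic acid signalling list (9 and 9 adjusted over the list alone), which did not pass (adjusted p = 0.935). The 3 lower ones were the phosphatase genes HAI1 (-0.38), HAI2 (-0.39) and HAI3 (-0.35), of which HAI2 and HAI3 were called at no single stage. The higher ones were the receptor genes PYR1 (0.255), PYL4 (0.475) and PYL6 (0.262). The other phosphatase genes in that list were not called: HAB1 (-0.226; adjusted p = 0.0614), AHG3 (-0.154), ABI2 (-0.128), HAB2 (-0.112), AHG1 (-0.091) and ABI1 (0.12). FWA, another gene silenced by DNA methylation, was called at no stage (0.15, 0.08 and 0.03).

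Of the 93 genes of the mitochondrial genome, 68 were lower in rdo5-1 siliques, 70 in dry seeds and 71 in imbibed seeds (medians -0.07, -0.19 and -0.12; p = 0.174, 0.0400 and 0.141 with an estimated correlation).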
